A study of Streptococcus salivarius with 24 samples.

How the data were processed

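RNA from 12 Streptococcus salivarius strains was sequenced in 2 libraries per strain, prepared with a stranded TruSeq mRNA kit per the labels' protocols. How ribosomal RNA was removed, the aligned genome build, the annotation, the counting tool and its strand setting are not given in the sources used here. The submitters' processing notes name cutadapt and Bowtie2 2.5.4 without a role or order. The authors deposited 1 table of raw counts, whole numbers per gene ID and library, with no normalization visible in the values. All 24 columns were matched to samples by strain and replicate number, and 0 columns and 0 rows were left out. One set of gene IDs served all strains, and the sources used here do not say which genome the reads were aligned to, so low counts can reflect sequence or gene content as well as expression.

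Total counts ran from 9450378 to 15267536 per library. Reads without molecular identifiers are not independent molecules, so floors of 3 counts cover counting error only. Libraries were first compared for identity. The lowest chi-square per degree of freedom between counts of any 2 libraries, over IDs with a summed count of at least 20, was 82.0, far above sampling noise, and all 24 libraries were kept as separate samples.

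Tests were run with edgeR 4.0.16 in R 4.3.3 on the counts as deposited: filterByExpr by strain (1899 of 1914 IDs kept), TMM normalization, 1 model with a mean per strain over all 24 libraries (12 residual degrees of freedom), and the quasi-likelihood F-test. Adjusted p-values are Benjamini-Hochberg over IDs within a test. The comparison among strains tested any difference among 12 means. Each strain was tested against the equally weighted mean of the other 11, and each of 66 pairs of strains against each other. In these an ID was called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. Standard errors of log2 fold changes were derived from the F statistic. CPM are relative to TMM-scaled library sizes. TMM factors ran from 0.809 to 1.11, and the median log2 fold change over all IDs was between -0.01 and 0.09 in the 12 strain contrasts. Library distances used log2 CPM with a prior count of 2, with 100000 permutations of strain labels. Adjacency of IDs was taken from the numbers in the locus tags, all multiples of 5. That these follow gene order is an assumption, tested in the closing section.

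The test scripts were tested on simulated counts, drawn from means, dispersions and library sizes of these data with 200 of the more abundant IDs changed. IDs were drawn independently of each other, and a true 2-fold change lies at the limit for a call. For 1 strain against the other 11 (1891 IDs), all strains shared the same means apart from the changed IDs, unlike the real strains. There, 44% of 2-fold, 100% of 4-fold and 98% of 8-fold changes were called, and 6 of 128 calls were false. For the pair KSS2 and KSS3 (1899 IDs), KSS3 was given the means of KSS2, and 2 of 89 calls were false. These figures check the scripts and are not error rates of the real contrasts.

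The near-identical pairs, with at most 10 IDs called, were also picked after the data were seen. The design, the main alternatives and the rule for named genes were fixed before the data were examined. The rule asked for a gene symbol or product, and the table has 0 columns of names. It was therefore applied without that requirement and kept shorter: for each strain, the called ID with the largest positive and the one with the largest negative log2 fold change among IDs with more than 10 counts in every strain and both libraries beyond all 22 others; among strains, the 2 IDs with the widest range of strain means; and the 2 most abundant IDs. Stretches of adjacent IDs, the shuffling of runs of called IDs and the IDs called between KSS1 and KSS11 were chosen after their values were seen. The 26 gene lists fixed in advance could not be filled, so gene set tests were not run, nor was the alternative without structural RNA genes.

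Alternatives were DESeq2 1.42.0, RLE factors, no low-count filter, a replicate block, removal of IDs with 10 or fewer counts in any strain, adjustment over all 12 contrasts, other distance settings, other limits for not detected IDs and leaving out each library. Chosen after seeing the data were the removal of 2 abundant IDs that varied between replicates, contrasts without each strain's nearest strain, and fits of single pairs with replicate block, for strain and for its interaction with the replicate number. Permutations were run in Python 3.11.15.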

Results

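Gene expression was measured by RNA sequencing in 12 strains of Streptococcus salivarius, a commensal bacterium of the human mouth. The strains, named KSS1 to KSS12, were oral isolates. Each was grown anaerobically at 37 °C in brain heart infusion, a rich broth, and harvested at an optical density at 600 nm of 0.5 to 0.7. There were 2 libraries per strain, 24 in all. The labels do not say whether these came from separate cultures, so the p-values below measure the spread between these libraries, which may be technical. The table gave read counts for 1914 gene IDs, all with the locus tag prefix BUB10_RS. The files do not pair these IDs with gene names or products, so genes are given by ID alone and no pathway could be named. Totals ran from 9450378 to 15267536 counts per library, with a median of 13625183. The 10 most abundant IDs of each library held 11.1% to 20.5% of its counts. Between 84 and 187 IDs had 0 counts in a library.

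The most abundant ID was BUB10_RS06205, at 27673 CPM (counts scaled to library size) ± 5829 (SD of the 12 strain means). It did not pass the test for a difference among strains (edgeR adjusted p = 0.308). BUB10_RS02985, the second most abundant, did (edgeR adjusted p = 0.00536), and its strain means ran from 9725 to 44941 CPM.

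The first question was whether strains differed by more than libraries of 1 strain. They did for the set as a whole. The mean Euclidean distance in log2 CPM was 30.6 between the 2 libraries of a strain and 93.8 between libraries of different strains, a ratio of 0.326. None of 100000 random assignments of strain labels gave so low a ratio, and their lowest was 0.562 (one-sided permutation test, p = 1e-05, the smallest these permutations can give). Much of the distance between strains came from IDs with 10 or fewer counts in some strain. Without them the mean distances were 27.1 and 47.0, a ratio of 0.577, against a lowest permuted ratio of 0.673 (one-sided permutation test, p = 1e-05). KSS7 lay farthest from the others, at a mean distance of 126 against 86.3 to 96.7 for the other 11 strains. Distances within strains ran from 17.8 in KSS8 to 46.7 in KSS4.

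Strain labels did not always give the nearest library. Only 9 of the 24 libraries had the other replicate of their own strain as their nearest neighbour. The other 15 were nearest to a library of 1 other strain, always within the pairs KSS1 and KSS11, KSS2 and KSS3, KSS4 and KSS5, or KSS6 and KSS12. In 11 of these 15 the nearest library carried the same replicate number. The 4 libraries of KSS6 and KSS12 were each nearest to the library of the other strain with the other number. KSS1 replicate 1, for example, lay 18.0 from KSS11 replicate 1 and 25.2 from KSS1 replicate 2.

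**Figure D1:**
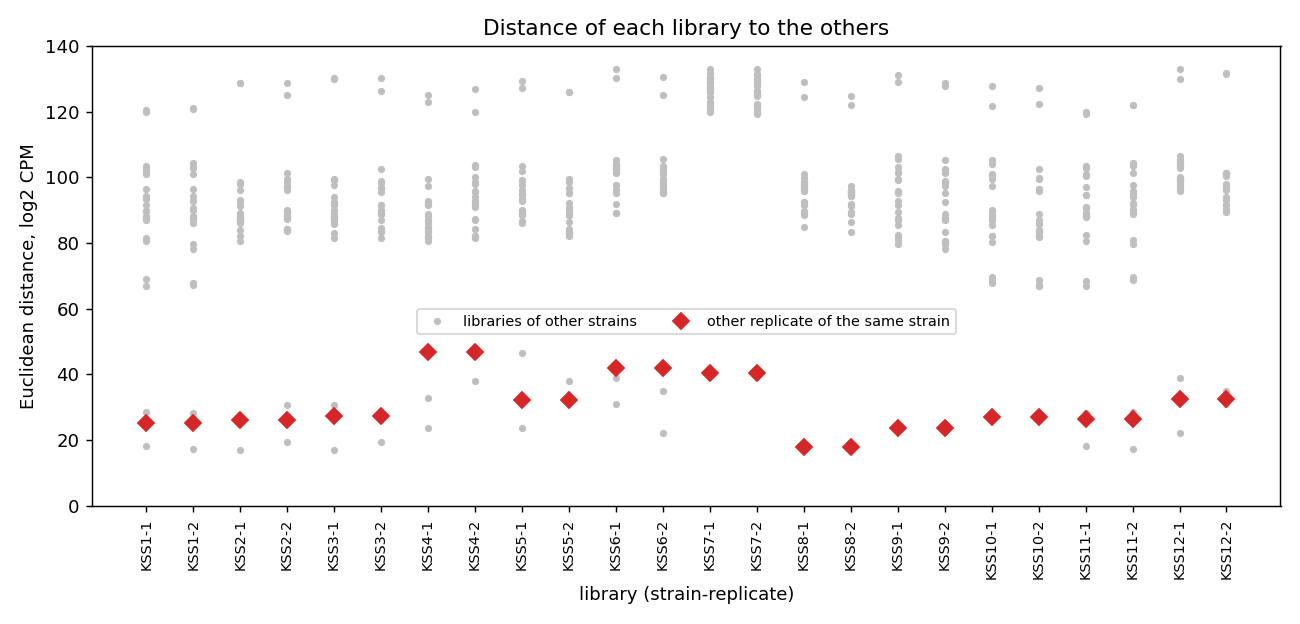
Euclidean distance in log2 CPM (vertical axis) from each of the 24 libraries (horizontal axis, strain and replicate number) to the other replicate of its strain (red diamonds) and to each library of the other strains (grey points). Grey points lie below the diamond for 15 libraries, and KSS7 has a mean distance of 126 to the other strains.

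Counts of most IDs differed among the 12 strains, which can reflect sequence or gene content as well as expression. Of 1899 IDs tested, 1263 (66.5%) passed the edgeR quasi-likelihood F-test for any difference among strain means at an adjusted p of 0.05. Of the 1577 IDs with more than 10 counts in every strain, 947 (60.1%) passed, including IDs with few reads in a strain. Among these, BUB10_RS05185 had the widest range of strain means, from 1.52 CPM ± 0.00413 (SD, n = 2) in KSS8 to 8539 ± 5493 (SD, n = 2) in KSS1 (edgeR adjusted p = 1.94e-06). BUB10_RS08185 came second, from 0.827 CPM ± 0.122 (SD, n = 2) in KSS5 to 2164 ± 767 (SD, n = 2) in KSS12 (edgeR adjusted p = 8.47e-10). The biological coefficient of variation between libraries of a strain, estimated over all IDs, was 33.6%.

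Some genes gave almost no reads in particular strains. An ID was called not detected in a strain when its counts over both libraries summed to 3 or fewer while at least 6 other strains had 20 or more counts in each library. This held for 163 IDs in at least 1 strain. Of these, 86 were not detected in exactly 1 strain and 77 in 2 or more. KSS7 had 97 such IDs, and the other strains had from 11 (KSS4) to 31 (KSS9). A sum of 3 counts corresponds to 0.0985 to 0.148 CPM, depending on the depth of the strain, and covers counting error only. The reads show that these transcripts were not detected at this depth. They do not show whether the gene was missing, too different in sequence to be counted, or not transcribed.

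Undetected IDs lay next to each other in the order of ID numbers. In KSS7, 59 pairs of adjacent IDs were both undetected, against a mean of 4.84 and a maximum of 15 over 10000 shufflings of positions (one-sided permutation test, p = 0.0001, the smallest these permutations can give; adjusted p = 0.000109 over 12 strains). Adjacent pairs were also more frequent than under shuffling in each of the other 11 strains (2 to 10 pairs; permutation adjusted p of 0.0016 or less). The longest stretch in KSS7 held the 13 IDs from BUB10_RS01925 to BUB10_RS01985, which summed to 3 counts there. Only 5 of the other strains had 20 or more counts per library in each of them. The 11 IDs from BUB10_RS09705 to BUB10_RS09795 summed to 4 counts in KSS7, and their median level in the other strains was 506 CPM. The 10 IDs from BUB10_RS02265 to BUB10_RS02310 had 0 counts in KSS7 and at least 674 counts each in every other strain.

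Other stretches divided the strains in groups. The 13 IDs from BUB10_RS08555 to BUB10_RS08615 had 0 counts in 9 strains and were read in KSS6, KSS8 and KSS12, where each had at least 300 counts per strain and their median level was 266 CPM. The 8 IDs from BUB10_RS08290 to BUB10_RS08325 were read in KSS2, KSS3, KSS4 and KSS5 only, with at most 1 count per ID in any other strain. The 7 IDs from BUB10_RS04525 to BUB10_RS04555 were read in KSS2, KSS3, KSS6, KSS9 and KSS12. The 5 IDs from BUB10_RS08860 to BUB10_RS08880 were read in KSS2 and KSS3 alone, at a median of 2.82 CPM.

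**Figure D2:**
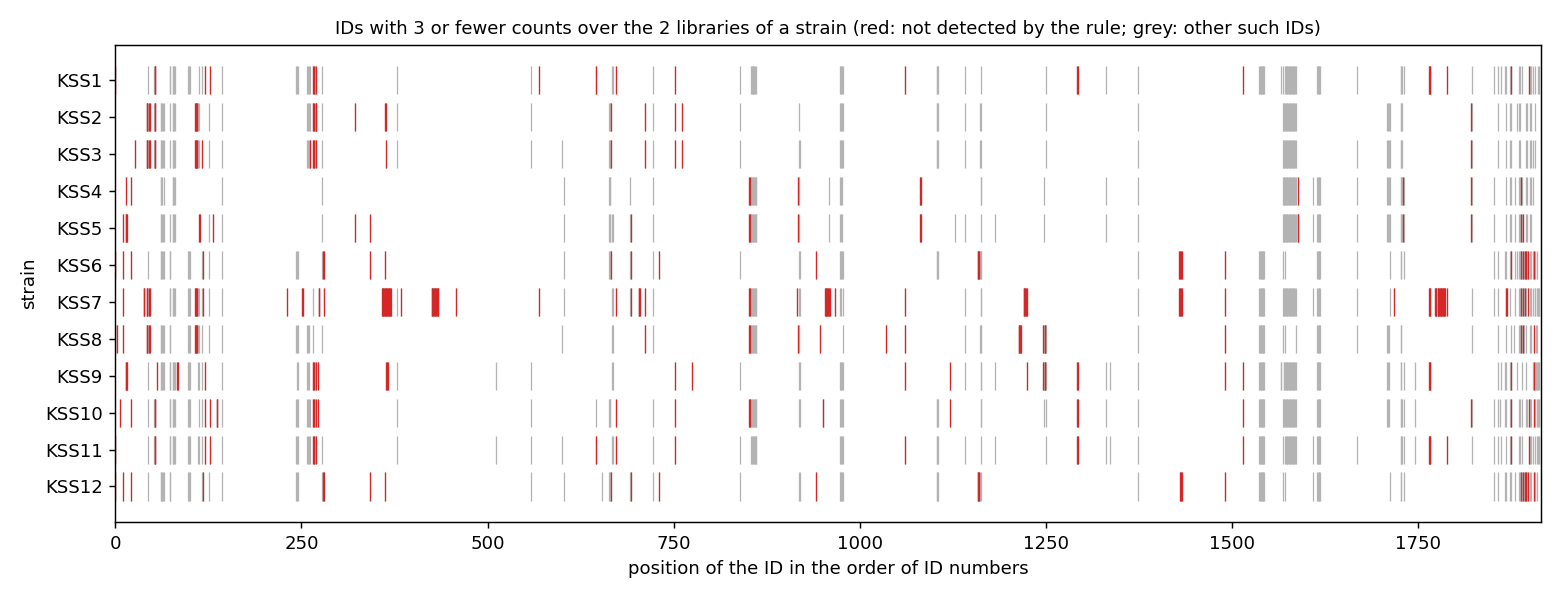
Each row is a strain and each vertical mark an ID with 3 or fewer counts over the strain's 2 libraries, placed in the order of ID numbers (horizontal axis). Red marks met the rule for not detected (97 in KSS7, 11 to 31 in the other strains) and grey marks are IDs for which fewer than 6 other strains had 20 or more counts in each library.

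Each pair of strains was then compared. The 66 comparisons called a median of 355 IDs, and up to 589 (KSS7 and KSS9), at an edgeR adjusted p under 0.05 with at least a 2-fold difference. Between 4 pairs of strains almost nothing was called. No ID was called between KSS2 and KSS3, between KSS4 and KSS5, or between KSS6 and KSS12 by edgeR or by DESeq2. At an unadjusted edgeR p under 0.05 these pairs had 25, 64 and 58 IDs, fewer than chance alone would give among 1899. These numbers are therefore no sign of differences, and the main tests were conservative for these pairs. Fits of each pair's 4 libraries alone with replicate block had 295, 55 and 12 such IDs in turn. Without KSS4 replicate 2, 4 IDs were called between KSS4 and KSS5, and a fit of the 4 libraries of KSS2 and KSS3 alone with replicate block called 4. The other 62 pairs had at least 199 IDs called. The same 4 pairs, picked by their few calls, had 0 discordant IDs, meaning IDs with 3 or fewer counts in 1 strain and 20 or more in each library of the other. The other 62 pairs had 35 to 158, of which 99.9% were also called, so discordance is not separate evidence. Power for small differences was limited. In counts simulated for the KSS2 and KSS3 comparison over 1899 IDs, 12% of 2-fold, 70% of 4-fold and 92% of 8-fold changes were called.

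KSS1 and KSS11 differed in 4 IDs, which form 2 adjacent couples. BUB10_RS09335 had 39 and 26 counts in the KSS1 libraries and 8191 and 4804 in those of KSS11, a 212-fold difference (log2 fold change, KSS1 minus KSS11, -7.73 ± 0.80 (SE), edgeR adjusted p = 0.00121). BUB10_RS09340 had 20 and 12 counts in KSS1 and 1031 and 1844 in KSS11 (edgeR adjusted p = 0.0232). BUB10_RS00885 was 7.17-fold higher in KSS1, with 461 and 379 counts against 59 and 49 (edgeR adjusted p = 0.00029). BUB10_RS00880 was 2.95-fold higher in KSS1 (edgeR adjusted p = 0.0425). The 4 IDs were chosen after their values were seen, as the only ones called. Without either library of KSS1 the count fell to 1, and to 2 without KSS8 replicate 1, KSS11 replicate 2 or KSS12 replicate 2.

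**Figure D3:**
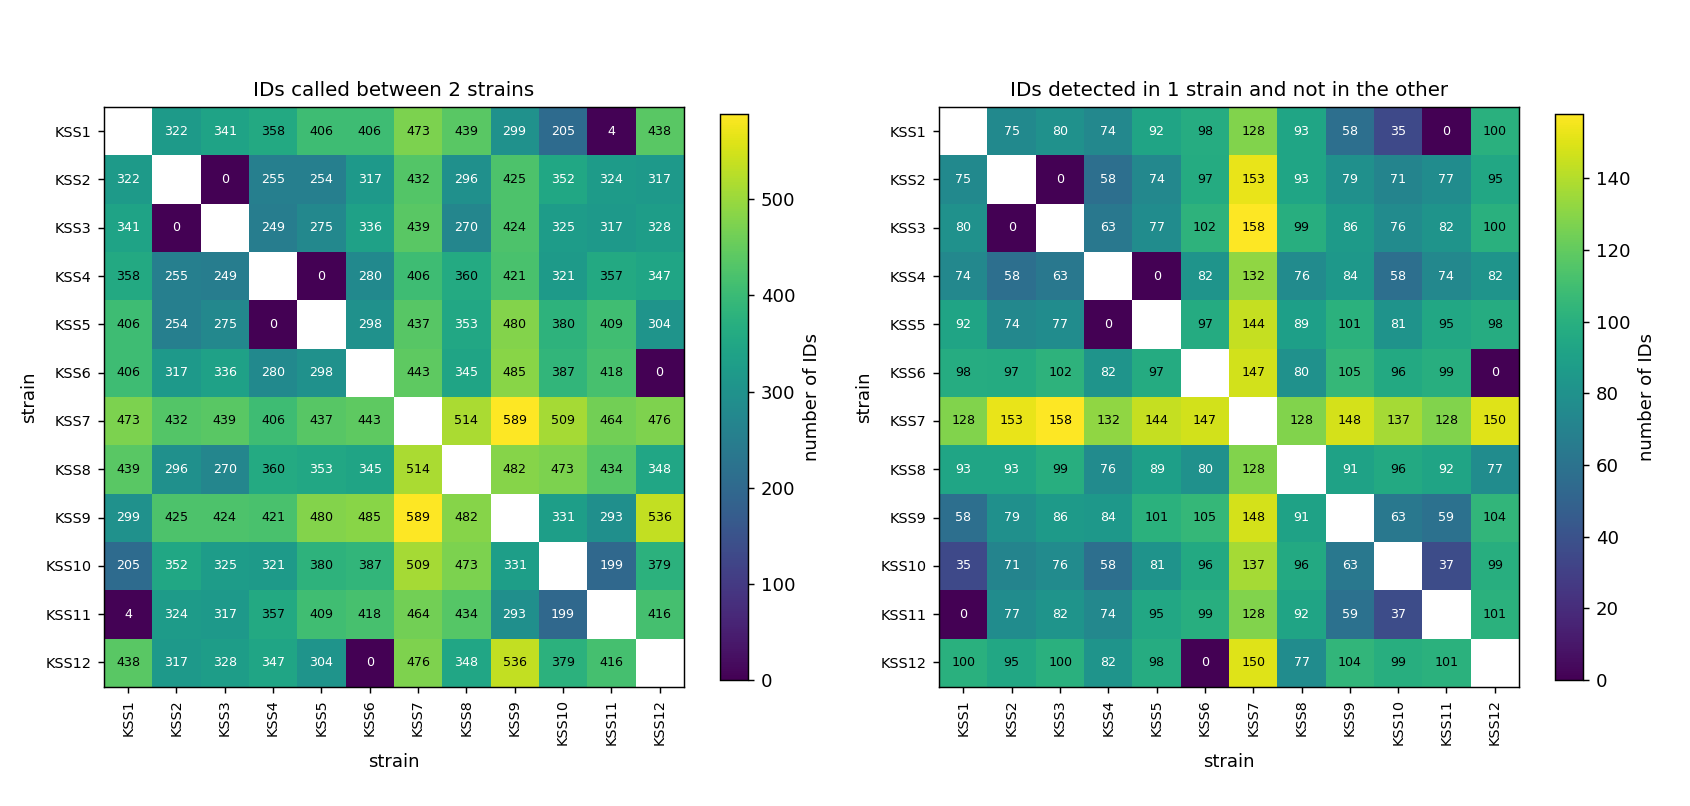
Matrices of the 12 strains against each other, with the number of IDs called between 2 strains by edgeR (left) and the number of discordant IDs, detected in 1 strain and not in the other (right); colour gives the same number. The 4 pairs KSS1 and KSS11, KSS2 and KSS3, KSS4 and KSS5, and KSS6 and KSS12 have 0 to 4 called and 0 discordant IDs, and the other 62 pairs have at least 199 and at least 35.

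No strain is named as a reference in the labels, so each was set against the mean of the other 11. KSS7 had 215 IDs called higher and 194 lower. KSS9 had 217 higher and 184 lower, and KSS8 had 284 higher and 110 lower. KSS5 had 279 and 59, KSS12 had 262 and 67, KSS6 had 252 and 60, KSS10 had 176 and 119, and KSS4 had 225 and 50. KSS11 had 189 higher and 81 lower, KSS1 had 190 and 72, KSS3 had 195 and 62, and KSS2 had 191 and 54. The order of KSS7 and KSS9 turned with DESeq2, which called 466 and 469 IDs in them. These are edgeR calls at an adjusted p under 0.05 with at least a 2-fold difference. The contrasts are not independent, since each strain is part of the mean for the rest, and the 8 strains of the near-identical pairs are also set against their partner.

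Higher calls outnumbered lower calls in all 12 strains in the main edgeR fit. Many of the higher calls were IDs with 10 or fewer counts in another strain, with the lowest share in KSS7, 94 of 215, and the highest in KSS3, 144 of 195. Among IDs with more than 10 counts in every strain, KSS7 had 121 higher and 117 lower, KSS8 had 117 and 95, and KSS5 had 110 and 47. In KSS9 the balance turned, with 92 higher and 162 lower, as it did in KSS10, with 61 and 106, in KSS11, with 71 and 73, and in KSS3, with 51 and 53. An edgeR fit without the IDs with 10 or fewer counts in any strain had more lower than higher calls in KSS7 (112 higher and 115 lower), KSS9 (87 and 161), KSS10 (56 and 103) and KSS11 (66 and 72). In KSS7, 75 of the 194 lower calls were IDs with 10 or fewer counts in that strain. The balance also depended on the tool. The share of calls that were higher ran from 52.6% to 82.5% over strains with edgeR and from 41.4% to 70.6% with DESeq2. For KSS1 to KSS12 in turn it was 56.1%, 59.2%, 59.7%, 65.6%, 70.6%, 66.8%, 41.4%, 61.6%, 46.9%, 46.6%, 54.9% and 67.2% with DESeq2, so lower calls were the majority in KSS7, KSS9 and KSS10.

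**Figure D4:**
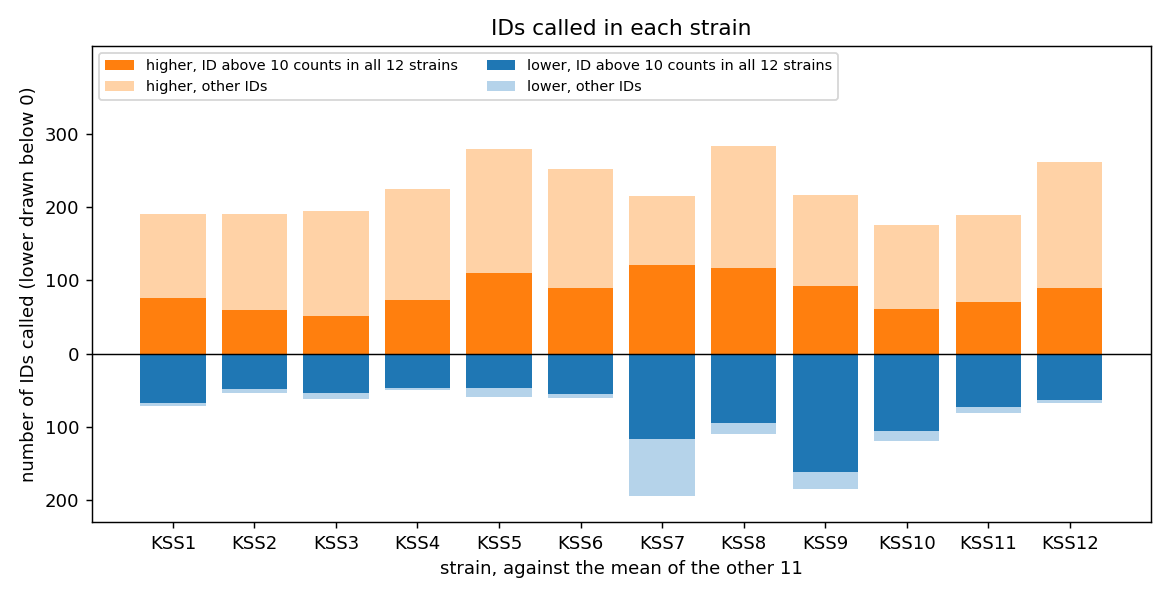
Number of IDs called in each strain (horizontal axis) against the mean of the other 11, with higher calls above 0 and lower calls drawn below 0. Dark bars are IDs with more than 10 counts in all 12 strains, pale bars the others; KSS9 has 92 higher and 162 lower in the dark bars.

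The 4 strains outside the near-identical pairs had the most IDs with both libraries beyond all 22 others, which a strain with a close partner can rarely reach. Among called IDs with more than 10 counts in every strain, these numbered 47 higher and 68 lower in KSS7, 51 and 45 in KSS8, 40 and 76 in KSS9, and 11 and 36 in KSS10. Chance would give 0.362% of IDs in each direction, or 5.71 of 1577, before any test. Fold changes against the other strains compare means of log2 levels, so they can exceed the ratio of mean CPM. In KSS7 the top such ID was BUB10_RS00615, at 194 CPM ± 76.7 (SD, n = 2) and at most 40.3 in any library of another strain, which was 17.4-fold higher (log2 fold change 4.12 ± 0.29 (SE), edgeR adjusted p = 7.97e-09). The lowest was BUB10_RS01755, with 5 and 11 counts in KSS7 (0.561 CPM ± 0.177, SD, n = 2) against a mean of 463 CPM elsewhere (edgeR adjusted p = 1.38e-08). KSS8 had BUB10_RS01435 at 64.7 CPM ± 11.2 (SD, n = 2) and at most 39.2 elsewhere, and BUB10_RS05185 with 15 and 18 counts against a mean of 1935 CPM in the other strains. In KSS9, BUB10_RS06090 reached 1977 CPM ± 423 (SD, n = 2) against a mean of 145 CPM elsewhere (23.5-fold by mean logs, edgeR adjusted p = 2.66e-09), and BUB10_RS07075 had 30 and 10 counts against a mean of 882 CPM elsewhere. In KSS10, BUB10_RS10225 reached 360 CPM ± 107 (SD, n = 2) against a mean of 19.0 CPM elsewhere and at most 189 in any library (63.9-fold by mean logs, edgeR adjusted p = 9.17e-09). BUB10_RS00050 had 10 and 9 counts there (edgeR adjusted p = 0.0142), a call that was lost without either KSS10 library.

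The strains of the near-identical pairs had 1 to 9 such IDs in each direction. As no ID was called between KSS2 and KSS3, KSS4 and KSS5, or KSS6 and KSS12, those named for these strains are not shown to separate partners. BUB10_RS10280 was 12.9-fold higher in KSS2, at 66.5 CPM ± 1.57 (SD, n = 2; edgeR adjusted p = 1.31e-09), and BUB10_RS05125 was lower at 8.91 CPM ± 1.31 (SD, n = 2), a call lost without either KSS2 library. In KSS3, BUB10_RS08960 stood at 121 CPM ± 29.6 (SD, n = 2) against a mean of 28.9 in the others, and BUB10_RS07645 at 1.38 ± 0.0565 (SD, n = 2) against 7.99. The highest library of another strain reached 50.6 CPM for BUB10_RS10280 and 97.9 CPM for BUB10_RS08960. In KSS6, BUB10_RS10420 was 10.3-fold higher and BUB10_RS00530 10.2-fold lower (edgeR adjusted p = 3.28e-06 and 3.26e-07). In KSS12, BUB10_RS01300 was 2.47-fold higher, a call lost without KSS12 replicate 2, and BUB10_RS04985 was 5.20-fold lower.

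In KSS1, BUB10_RS03585 was 3.75-fold higher (edgeR adjusted p = 3.41e-06), and BUB10_RS01615 was 3.86-fold lower (edgeR adjusted p = 0.0329), a call lost without either KSS1 library. In KSS11, BUB10_RS04860 was 4.44-fold higher and BUB10_RS00885 6.61-fold lower (edgeR adjusted p = 0.00026 and 2.1e-06). In KSS4, BUB10_RS02350 was 2.09-fold higher, a call lost without either KSS4 library or without KSS9 replicate 1, and BUB10_RS05135 was lower with 6 and 7 counts. In KSS5, BUB10_RS07455 was 3.46-fold higher and BUB10_RS03795 was lower with 4 and 10 counts. BUB10_RS02350 had a mean of 81.2 CPM in KSS4 and at most 72.1 in any library of another strain. BUB10_RS07455 had a mean of 54.0 CPM in KSS5 and at most 45.1 elsewhere.

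Runs of adjacent IDs also moved together among IDs read in all strains, though some had few reads in a strain. There were 25 runs of at least 4 adjacent IDs called higher in a strain and 17 called lower, each ID with more than 10 counts in every strain. Over 1000 shufflings of these IDs, alike in all strains, there were at most 3 in each direction (one-sided permutation tests, p = 0.000999, the smallest these permutations can give). Shuffling also breaks correlation between neighbours that does not follow strain. Differences between the 2 libraries of a strain correlated between adjacent IDs at a median r of 0.549. These p-values therefore do not separate strain effects from such shared spread. The runs lay at 21 distinct stretches, and some were shared by both strains of a near-identical pair. The 4 IDs from BUB10_RS01750 to BUB10_RS01765 gave 5 of the 25 higher runs (KSS1, KSS8, KSS9, KSS10 and KSS11). KSS7, at a median log2 fold change of -9.06 and as few as 16 counts per ID, was in the mean these were set against. The 7 IDs from BUB10_RS07165 to BUB10_RS07195 were called higher in KSS5, KSS6 and KSS12, with median log2 fold changes of 1.52, 2.08 and 2.76. Their summed level was 170 CPM ± 82.6 in KSS12, 118 ± 56.0 in KSS6, 83.8 ± 22.1 in KSS5 and 39.3 ± 27.9 in KSS4, and at most 25.7 ± 6.69 in the other strains (SD, n = 2 each). The 7 IDs from BUB10_RS02650 to BUB10_RS02680 were higher in KSS9, at 1924 CPM ± 12.9, and lower in KSS12, at 277 ± 58.3 (SD, n = 2 each). Its partner KSS6 stood at 372 CPM ± 162 (SD, n = 2), with a library at 258, inside the KSS12 range of 235 to 318. The 6 IDs from BUB10_RS07775 to BUB10_RS07800 were higher in KSS1, at 3558 CPM ± 545 (SD, n = 2), and the first 5 of them also in KSS11. The 6 from BUB10_RS09915 to BUB10_RS09940 were higher in KSS7, at 4554 CPM ± 865 (SD, n = 2), and the last 5 of them also in KSS8. A KSS9 library reached 3933 CPM, next to 3942 in the lower KSS7 library. The longest run, 12 IDs from BUB10_RS08885 to BUB10_RS08940, was called higher in KSS4, but its 2 libraries stood at 690 and 5038 CPM, and KSS10 and KSS7 reached 1519 and 1619 CPM in 1 library each.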

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

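The fits of single pairs, the removal of 2 abundant IDs and the contrasts without the nearest strain were chosen after the data were seen; the rest were planned. The number of IDs differing among strains was 1263, with 1429 by DESeq2, 1266 with RLE factors, 1278 without a filter, 939 after removing IDs with 10 or fewer counts in any strain, and 1113 to 1326 when 1 library was left out. That removal, which tests fewer IDs by construction, lowered the strain counts to 140 (KSS1), 98 (KSS2), 88 (KSS3), 113 (KSS4), 148 (KSS5), 144 (KSS6), 227 (KSS7), 209 (KSS8), 248 (KSS9), 159 (KSS10), 138 (KSS11) and 145 (KSS12), the median per pair from 355 to 200, and the count for KSS1 and KSS11 from 4 to 1. Under the other alternatives the total called in every strain stayed within 1.5 times its value. Lower calls alone moved more in some strains, with DESeq2 from 54 to 118 in KSS2 and 50 to 108 in KSS4, against 194 to 273 in KSS7. The removal moved the share of higher calls by up to 24.4 percentage points (KSS10), DESeq2 by over 10 in 11 strains and RLE factors by at most 2.64; the cause of the DESeq2 shift was not tested. Where a library was left out, its strain's lone library was assumed to vary like the other strains. This gave 1 to 4 IDs for KSS1 and KSS11, and 0 to 4 for KSS4 and KSS5 (4 without KSS4 replicate 2). A fit of the 4 libraries of KSS2 and KSS3 alone, with replicate block, called 4 IDs, all higher in KSS3, with the smallest adjusted p in BUB10_RS06810 and BUB10_RS00900. It called 3 for KSS1 and KSS11 and 0 for the other near-identical pairs. For KSS6 and KSS12 the block as labelled left shared variation in the residual, and the interaction of strain and number called 185 IDs (0 in the other 3 pairs). IDs at an unadjusted p under 0.05 for strain and for the interaction numbered 131 and 44 (KSS1 and KSS11), 295 and 22 (KSS2 and KSS3), 55 and 75 (KSS4 and KSS5), and 12 and 428 (KSS6 and KSS12). The number of IDs not detected in some strain fell from 163 to 68 when all 11 other strains had to have reads; the stricter rule itself accounts for this. It was 138 at exactly 0 counts and 124 with 100 counts required. The distance ratio stayed between 0.285 (Spearman) and 0.577 (IDs with 10 or fewer counts in any strain removed) over all settings, at permutation p = 1e-05, the smallest these permutations can give. Replicate numbers did not pair the libraries across all strains: replicate differences correlated above 0.1 in 29 of 66 pairs of strains and below -0.1 in 19. All of those below -0.1 involved KSS1, KSS10, KSS11 or KSS12. Among KSS2 to KSS9 every correlation was positive, from 0.0454 (KSS2 and KSS5) to 0.682 (KSS2 and KSS3). The 2 libraries of a strain mirror each other. Those of 11 of 12 strains correlated best with 1 of their own number. The mean was 6 over all exchanges of numbers within strains (exact p = 0.0137), a hint from the data and not the design. KSS12 was the exception, with a highest correlation of 0.127 (KSS1) and a lowest of -0.471 (KSS6). With a replicate block 1359 IDs differed among strains and no strain count moved by over 1.5 times. Of 720 values of the 24 IDs named per strain under alternatives, 0 changed sign and 10, all with 1 library left out, lost the call, in 5 IDs. These 24 IDs were picked from the main fit as its largest called changes, so kept signs and calls are not separate support. The removal of structural RNA IDs and the gene list tests with their alternatives were not run, since the IDs have no names.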

Other observations

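All tests of explanations in this part were chosen after the results were seen. The labels give no biological grouping of the strains beyond their names, and no genome of any strain was used here.

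Libraries of 1 strain could differ widely in a few abundant IDs. BUB10_RS10155 held 0.0243% of the counts in KSS5 replicate 1 and 2.42% in KSS5 replicate 2, and from 0.0376% to 2.78% between the KSS4 libraries. BUB10_RS03840 held 2.05% in KSS7 replicate 1 and 0.111% in replicate 2. BUB10_RS10170 had the largest spread of the 1899 IDs tested, with a pooled SD between libraries of a strain of 2.58 on the log2 scale. Without both BUB10_RS03840 and BUB10_RS10155, 1277 IDs differed among strains against 1263 with them. As each ID is tested singly, removing 2 of 1899 could change little, and BUB10_RS10170 was kept in.

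The near-absence of differences between KSS1 and KSS11, KSS2 and KSS3, KSS4 and KSS5, and KSS6 and KSS12 is the pattern most in need of a second look. It was not 1 library deposited under 2 names, since the lowest chi-square per degree of freedom between libraries of the paired strains was 82.0, and too few libraries is not the whole cause, as the same design called at least 199 IDs in each of the other 62 pairs, although most 2-fold differences would go unseen. That the strains of a pair are closely related isolates is a candidate explanation that stays open, because 99.9% of discordant IDs in the other pairs were also called, so pairs picked by few calls had to share their undetected IDs. For KSS1 and KSS11, 1 culture carried under 2 strain labels is argued against by 4 called IDs with both libraries of each strain apart. These were the only IDs called and form 2 adjacent couples. With 2 libraries per strain, libraries apart add little to the call itself. After removal of IDs with 10 or fewer counts in any strain, 1 ID was called. In the other 3 pairs the main fit called 0 and cannot tell this from close relatedness. A fit of the pair with replicate block called 3 such IDs for KSS2 and KSS3. Their interaction of strain and number, a split that does not follow strain, called 0. At an unadjusted edgeR p under 0.05 the IDs numbered 295 for strain and 22 for the interaction. This leans against 1 culture for KSS2 and KSS3, in a fit chosen after the data were seen. The rule set for this question left the pair undecided, since the interaction called 179 such IDs between KSS6 and KSS12. The fit with block called 0 for KSS4 and KSS5 and for KSS6 and KSS12, which decides nothing there.

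In 15 libraries the nearest library was one of the partner strain and not the other replicate. Noise independent from ID to ID is excluded, because replicate differences of adjacent IDs correlated with a median r of 0.549 across strains, against at most 0.0469 over 1000 shufflings (across genes, which are not independent replicates). A day or batch shared by libraries of 1 replicate number may account for 3 of the pairs. There, replicate differences correlated between partner strains at 0.73 (KSS1 and KSS11), 0.68 (KSS2 and KSS3) and 0.413 (KSS4 and KSS5). Such correlations were not particular to partners. They reached 0.680 for KSS4 and KSS6 and 0.628 for KSS6 and KSS7, while 19 of 66 pairs of strains lay below -0.1. All of those 19 involved KSS1, KSS10, KSS11 or KSS12, and among KSS2 to KSS9 no correlation was negative. With the numbers as labelled a shared batch does not account for KSS6 and KSS12, where the correlation was -0.471. KSS12 also stood at -0.346, -0.324 and -0.350 with KSS2, KSS3 and KSS4, but at 0.127 with KSS1. Exchanged numbers in KSS12, or a batch that does not follow the numbers, stay open for this pair. A difference in culture state within the harvest window was not tested.

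Too few reads in a strain is excluded for the undetected IDs, because the lowest strain total was 66.7% of the highest, while a fall to 3 from 40 counts, the least in a strain with 20 or more per library, needs 7.5%. Stretches lost or too different to align are a candidate explanation, as undetected IDs were adjacent more often than by shuffling in each strain (highest permutation adjusted p = 0.0016). Genes present but not transcribed cannot be told apart from lost ones, since neighbours may be silent together and the 80.5% of the 353 cases with exactly 0 counts fit both. The reading as stretches needs ID numbers to follow gene order, and strain means of adjacent IDs correlated with a median r of 0.454 (across genes) against at most 0.0413 over 1000 shufflings.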
